A study of Mus musculus with 11 samples.

How the data were processed

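LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of mouse bone marrow that holds stem cells and early progenitors, were sorted by flow cytometry from Klf5 knockout and wild-type mice. Per the labels and the series' design text, total RNA was labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with probes along its whole transcript. The labels name 5 knockout and 6 wild-type samples. The authors deposited log2 RMA signals in 2 tables that were normalized separately, one of 9 arrays and one of 2 arrays. Per the file headers these are gene-level signals with default settings, and per the submitters' processing notes they come from Affymetrix Expression Console; its version is not given in the sources used here. A deposited value table holds log2 values of all 11 arrays, and each of its columns equalled 1 column of the RMA tables within 5e-05, which tied the arrays of each genotype to the samples' replicate numbers. The genotype in each column name matched the sample label in every case.

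The 9-array table holds knockout replicates 2 to 5 and wild-type replicates 2 to 6, the 4 and 5 arrays that the series' design text counts, and it gave the main comparison. Knockout replicate 1 and wild-type replicate 1 are the 2-array table. The knockout and wild-type groups were tested within the 9-array table, all 11 arrays entered only the comparison of the tables and named alternatives, and values of the 2-array table are given beside them without a test. Of 35556 rows, 6612 control rows were left out (1324 positive, 5222 negative and 13 spike controls, and 53 undescribed rows among the control identifiers), and 28944 transcript clusters were tested. The annotation in the files is on NCBIM37. Symbols were updated through RefSeq accessions against GRCm38.p6, where 22173 tested rows matched and 2404 symbols changed, and no coordinates were used. Of the tested rows 25523 had 1 symbol, 2 had several and 3419 had none. Where a gene had several rows, the one with the highest mean was used.

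Differences are knockout minus wild type on the log2 scale, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, adjusted over 23 lists: 15 pathway lists and 8 lists of markers of other blood and stromal cells, of which 1 pathway list is not reported here. Sex-linked genes were read array by array. These lists, the limma, preset-correlation camera and fry tests and the rule for named genes were fixed before the data were examined. The camera test with an estimated correlation was not part of that plan. The rule took Klf5, Rab5a, Rab5b, Rab5c, Itgb1 and Itgb2, then per direction the 12 genes of largest difference past the adjusted threshold. Where fewer passed, it filled up with genes at unadjusted p under 0.05 whose groups did not overlap. It asked for 1 symbol and a higher-group mean above the median of all transcript clusters, passed over predicted genes, RIKEN clones, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments, and took up to 4 members of smallest p per list. For the 2-array table, a list's median was placed among 10000 random lists matched on expression.

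The fit was tested on simulated data with 50 rows changed at each of 4 sizes. It called 26% of rows changed 1.41-fold, 66% at 2-fold, 92% at 4-fold and 98% at 8-fold, with 5 unchanged rows called. The changed rows had means above the median, all 200 were changed together, and the noise was independent between rows. These shares may therefore be too high for the real data, where few or no rows pass. Array data carry no read depth, and the number of arrays limits the precision: the median standard error was 0.116. The labels do not say that each array is a separate animal, so the p-values measure the spread between these samples, which may be partly technical. Alternatives covered the value table, all 11 arrays with and without a table term, 2 normalizations, a filter on dim rows, the variance model, array weights, each array left out, replicate blocks, other thresholds and the methods' t-test. After the data were seen, 4 were added: a block from the number in the column names, Xist and Y-linked levels as covariates, leaving out arrays with both Xist and Y-linked signal, and leaving out the pair of arrays nearest to the 2-array table. Fits blocked on or run within a grouping of arrays taken from the first principal component were also made, and are not reported because the same values defined the grouping. Figures were drawn with matplotlib 3.10.9.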

Results

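Gene expression was measured in sorted LSK bone marrow cells of Klf5 knockout mice and wild-type mice on the C57BL/6 background; per the labels, both groups carry Mx1-Cre. Klf5 is a zinc-finger transcription factor, and the series' title ties it to bone marrow homing through Rab5 and the beta1 and beta2 integrins. The main comparison set 4 knockout arrays against 5 wild-type arrays, and 1 further array of each genotype was normalized apart. Median signals of the 9 arrays lay between 5.93 and 6.03, and those of the 2-array table were 6.43 and 6.40.

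Klf5 itself had a mean log2 signal of 6.69 ± 0.08 in knockout (SD, n = 4) and 6.89 ± 0.11 in wild type (SD, n = 5), a difference of -0.20 (95% interval -0.37 to -0.03). The highest knockout array, at 6.76, lay just under the lowest wild-type array, at 6.77. The difference did not pass adjustment (limma adjusted p = 0.916). In the 2-array table Klf5 was at 7.17 in knockout and 7.32 in wild type. The probe set covers the whole transcript, and which of its probes lie in the deleted part is not given in the sources used here, so this is a limited check of the labels.

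The Rab5 genes, which encode small GTPases of the early endosome, did not differ beyond the spread between arrays. Rab5a had a log2 difference of -0.19 (95% interval -0.59 to 0.20), Rab5b of -0.31 (-0.85 to 0.23) and Rab5c of 0.10 (-0.20 to 0.40). The limma adjusted p was 0.918 for Rab5a, 0.916 for Rab5b and 0.929 for Rab5c. A second row of Rab5b gave -0.21. With each array left out in turn, the Rab5a difference lay between -0.305 (without knockout replicate 5) and -0.031 (without knockout replicate 2). That of Rab5b lay between -0.540 (without knockout replicate 5) and -0.165 (without wild-type replicate 6). That of Rab5c lay between 0.009 (without knockout replicate 4) and 0.192 (without knockout replicate 2), and none of these passed. These intervals leave room for differences in either direction.

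**Figure D1:**
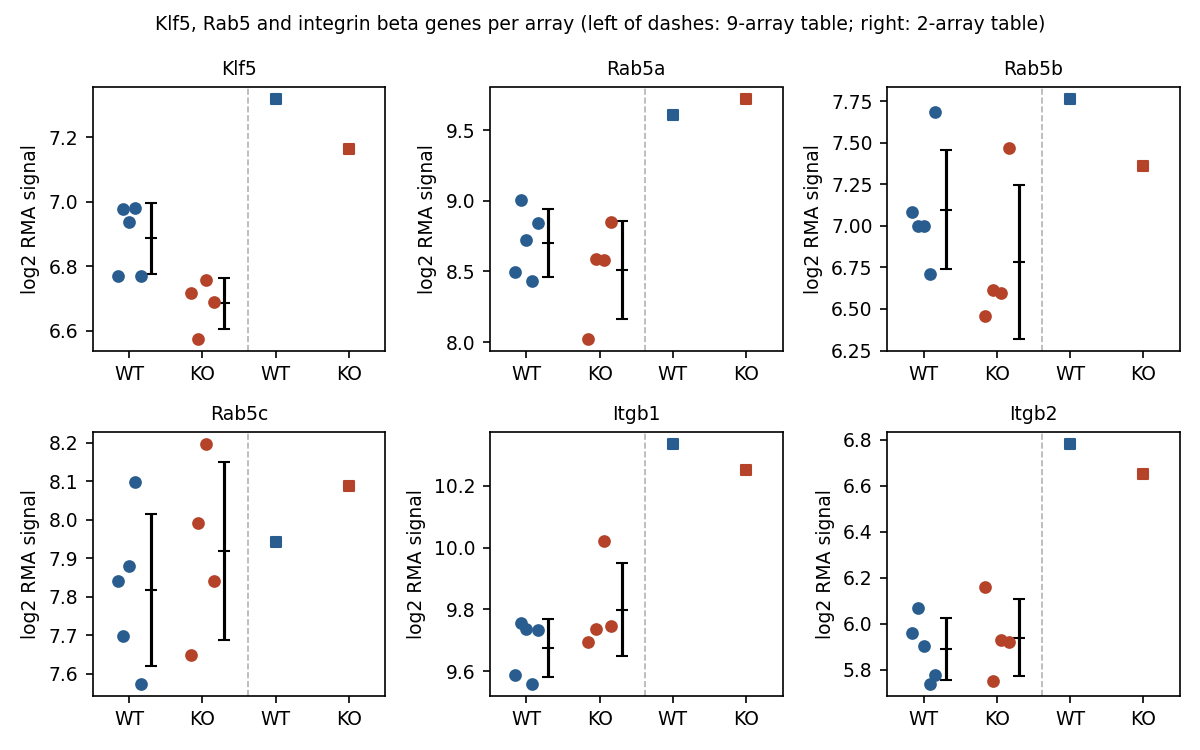
Log2 RMA signal of Klf5, Rab5a, Rab5b, Rab5c, Itgb1 and Itgb2, with 1 point per array and the mean ± SD beside the wild-type (WT, n = 5) and knockout (KO, n = 4) arrays of the 9-array table; squares right of the dashed line are the 2-array table, normalized separately. Klf5 is the gene of the 6 whose groups do not overlap, with 6.76 as the highest knockout value and 6.77 as the lowest wild-type value.

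Itgb1, the beta1 integrin subunit, had a mean of 9.80 ± 0.15 in knockout (SD, n = 4) and 9.67 ± 0.09 in wild type (SD, n = 5). Its log2 difference was 0.12 (95% interval -0.07 to 0.32, limma adjusted p = 0.916), a second Itgb1 row gave -0.06, and without knockout replicate 4 the difference was 0.051. Itgb2, the beta2 subunit of leukocyte integrins, differed by 0.05 (-0.18 to 0.28, limma adjusted p = 0.949), and by -0.02 without knockout replicate 2. For Itgb1 the interval excludes a change of 2-fold in either direction. That of Itgb2 does so for the signal only. Its means, 5.94 in knockout and 5.89 in wild type, lay below the median of all transcript clusters, 5.99. The negative-control medians of the 9 arrays were 5.27 to 5.62. So close to background, a 2-fold change in Itgb2 transcript is not excluded. The arrays measure transcripts and carry no information on protein at the membrane.

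Across all genes, no transcript cluster of 28944 passed the adjusted threshold in limma, and the lowest adjusted p was 0.907. At an unadjusted p under 0.05 there were 1181, with 420 higher and 761 lower in knockout, where 1447 would be expected by chance. The direction of this split depended on the scaling, as median centring of the arrays gave 695 higher and 445 lower. The methods' t-test gave 1150 unadjusted and 0 after Benjamini-Hochberg adjustment. The groups did not overlap in 285 transcript clusters, 0.985% of those tested, where chance gives 1.59%.

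The 24 genes named by the fixed rule therefore did not pass the test. Among those with higher values in knockout, Commd6 had a log2 difference of 1.41 ± 0.33 (SE) and Simc1 of 1.10 ± 0.23. Slc35a5, a solute carrier, had 0.76, Micu2, a regulator of the mitochondrial calcium uniporter, 0.72, and Arf2, a GTPase of membrane traffic, 0.70. The others were Phf12 at 0.63, Ccrl2 at 0.57, Spred2, an inhibitor of Ras signalling, at 0.52 (0.335 without wild-type replicate 5), Zfp790 at 0.47, Cnih1 at 0.47, Gna15 at 0.46 and Chchd3 at 0.46. The difference had the same sign in the separately normalized pair of arrays for 6 of these 12, against 44.6% of all tested rows. In that pair Commd6 differed by 0.035, and Spred2, the largest of the 6, by 0.278. Whether any of these 12 genes lies near Klf5, so that DNA linked to its allele could be the source, was not tested. In Simc1, Slc35a5, Arf2, Phf12, Ccrl2, Spred2, Gna15 and Chchd3, wild-type replicates 2 and 6 had the highest wild-type values. These replicates also had the highest Hbb-b1 in wild type. Commd6, Micu2, Zfp790 and Cnih1 did not show this. The groups barely separated in Phf12 (highest wild type 7.961, lowest knockout 7.965) and Spred2 (8.596 and 8.611). Whether structure other than genotype gives these differences was not tested.

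Klk1b21, a member of the glandular kallikrein family of serine proteases, had the lowest p of the named genes. It was at 5.85 ± 0.17 in knockout (SD, n = 4) and 6.80 ± 0.22 in wild type (SD, n = 5), a log2 difference of -0.95 (95% interval -1.24 to -0.66, limma adjusted p = 0.907). Its relative Klk1 had a difference of -0.38. Hnrnpa0, an RNA-binding protein, had -0.43, Tram2 -0.41 and Mrpl14, a mitochondrial ribosomal protein, -0.40. The remaining genes with lower values in knockout were Parp12 at -0.36, Rpusd3 at -0.35 (-0.220 without knockout replicate 2), Rhox9 at -0.35, Glis2 at -0.35, Shisa9 at -0.34, Shmt1, an enzyme of folate metabolism, at -0.34 and Naglu at -0.34. For 5 of these 12 the sign was the same in the separately normalized pair, against 44.6% of all tested rows.

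**Figure D2:**
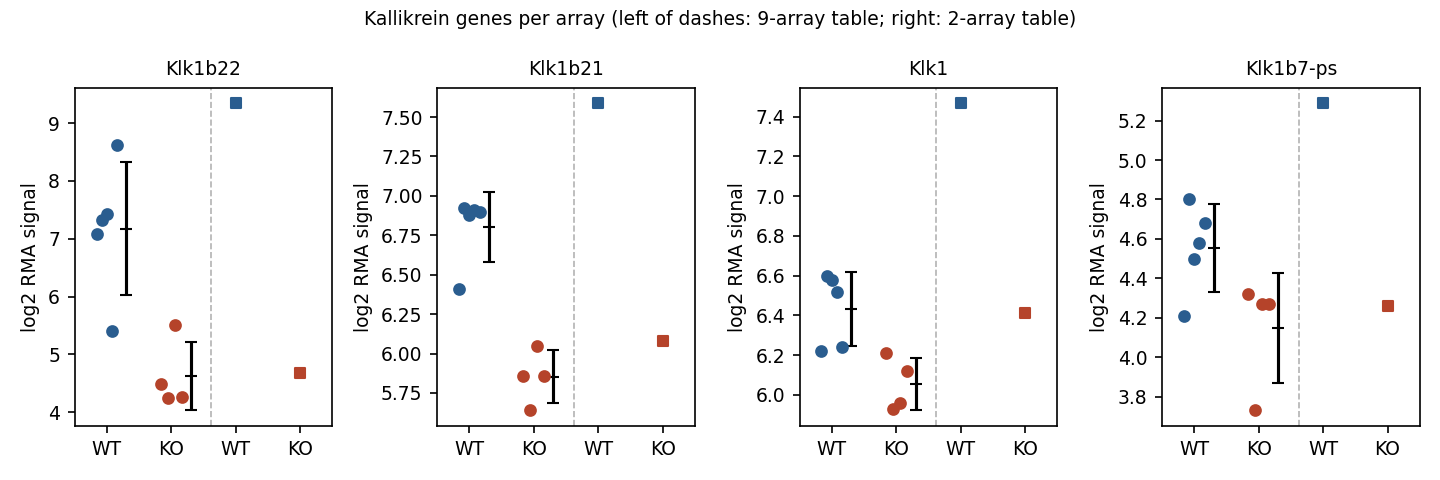
Log2 RMA signal of Klk1b22, Klk1b21, Klk1 and Klk1b7-ps, with 1 point per array and the mean ± SD beside the wild-type (WT, n = 5) and knockout (KO, n = 4) arrays; squares right of the dashed line are the 2-array table, normalized separately. Klk1b22 and Klk1b7-ps were chosen after their values were seen; Klk1b22 lies between 4.25 and 5.50 in knockout, below the negative-control median of the array in 4 of 4, and between 5.40 and 8.62 in wild type, while Klk1b7-ps lies below that median in 4 of 4 knockout and 5 of 5 wild-type arrays.

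**Figure D3:**
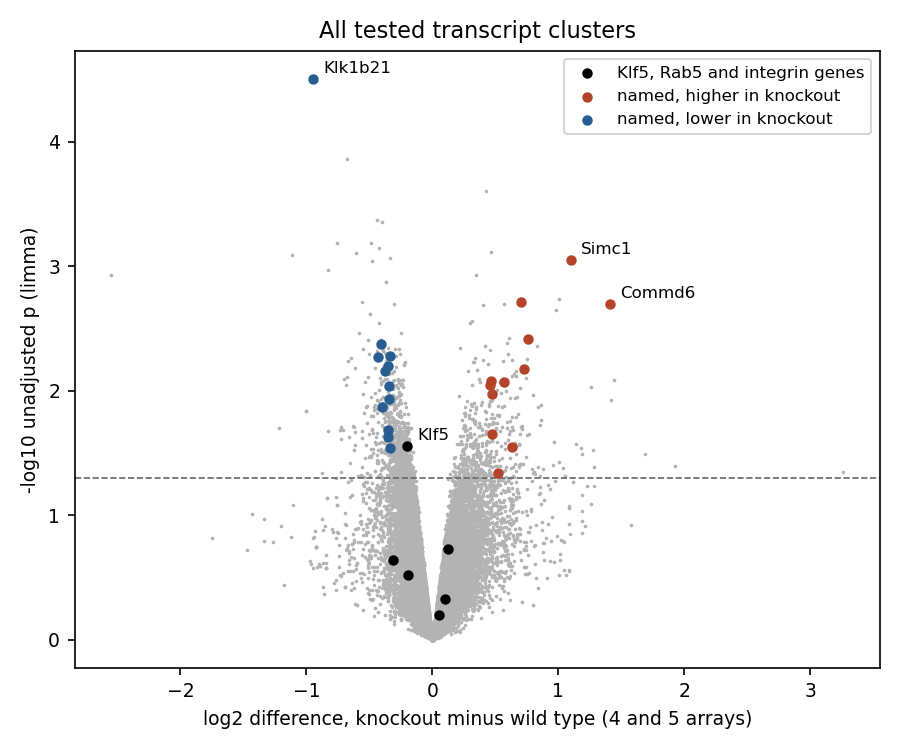
Each point is 1 of 28944 transcript clusters, with the log2 difference (knockout minus wild type, 4 and 5 arrays) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; the dashed line marks the unadjusted threshold of 0.05. Klk1b21 stands highest among the named genes at a difference of -0.95, and no point passes the adjusted threshold.

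The lists on Rab5, endocytosis and integrins were centred near 0. Of 30 genes of the Rab5 and early endosome list, 16 had higher and 14 lower values in knockout, with a median log2 difference of 0.02 and a camera adjusted p of 0.720. Rab31, at 0.42, had the smallest p of its members. Among 26 integrin subunits 14 were higher and 12 lower, with a median of 0.01 and a camera adjusted p of 0.720; Itgav was at 0.27 and Itga7 at -0.20. Clathrin coat and endocytosis genes had a median of 0.03, with Dnm1 at -0.29, and integrin activation and focal adhesion genes one of -0.02, with Crk at 0.34. Homing and adhesion receptors had a median of 0.03, with Ccr2 at 0.54 and Cdh5 at -0.19; this list passed, with higher values in knockout, without knockout replicate 2 (camera adjusted p = 0.0147, up to 0.996 over the alternatives). In that fit it did not pass, at adjusted p = 0.291 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone.

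Markers of other cell types stood at both ends of the list ranking. B cell markers had a median log2 difference of -0.20, with 17 of 22 lower in knockout, Cd79a at -0.48 and Cd22 at -0.24. The mean of the B cell list was 5.47 and 5.36 in knockout replicates 2 and 5 and 5.60 and 5.95 in wild-type replicates 2 and 6, the 4 of the 9 arrays with the highest Hbb-b1 and interferon list means. It was 5.13 and 5.12 in the other knockout arrays and 5.17, 5.18 and 5.21 in the other wild-type arrays, so this list moved with the array structure shared with Hbb-b1 and interferon genes in both genotypes. Within both sets of arrays each knockout value lay below each wild-type value. In the set with the lower means, every list mean lay below the negative-control median of its array. Those medians were 5.62 and 5.58 in knockout replicates 3 and 4, and 5.33, 5.33 and 5.29 in wild-type replicates 3, 4 and 5. The order within that set is therefore weak. That structure was neither shown to account for the lower values in knockout nor excluded. Stromal and endothelial markers had a median of -0.08, with 18 of 20 lower and Cdh5 at -0.19, against 0.11 in the 2-array table. Mast cell, basophil and eosinophil markers had a median of 0.05, with 14 of 18 higher and Mcpt8 at 0.73, and neutrophil and granule markers one of 0.07, with Ctsg at 0.62. None of the 23 lists passed: the camera adjusted p was 0.130 for B cell and for stromal and endothelial markers, 0.135 for the mast cell list and 0.381 for the neutrophil list. With an estimated correlation the lowest adjusted p was 0.893. This count was not stable. It was 8 without knockout replicate 2, with homing, oxidative phosphorylation, megakaryocyte, cell cycle, neutrophil and mast cell lists higher and B cell and stromal lists lower. None of the 8 passed in that fit, with a lowest adjusted p = 0.291 with an estimated correlation. It was 3 without knockout replicate 5, with the mast cell list higher and the interferon and stromal lists lower, and 2 without wild-type replicate 4, with the mast cell list higher and the B cell list lower. In these fits the lowest was adjusted p = 0.933 and adjusted p = 0.765 with an estimated correlation, so no call passed in both forms of the test. The form with an estimated correlation called no list in any fit and was not tried on simulated data. It therefore cannot show that a call is false.

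The remaining lists did not pass the threshold either. Oxidative phosphorylation genes had a median of 0.05 (camera adjusted p = 0.246), cell cycle genes 0.03 (0.635), interferon response genes -0.02 (0.720), KLF and SP family genes -0.05 (0.629) and erythroid markers 0.02 (0.629). Stem cell genes had a median of -0.04 (0.843), with Tek at 0.34 and Kit at -0.17, and multipotent progenitor genes 0.02 (0.790), with Sox4 at -0.24. The camera adjusted p was 0.720 for megakaryocyte markers, T and NK cell markers and apoptosis genes, 0.725 for immediate early genes, 0.726 for clathrin genes, 0.828 for late endosome Rab and focal adhesion genes, 0.837 for monocyte markers and 0.431 for homing receptors. The test pointed up where the median lay below 0 for T and NK cell markers, immediate early, late endosome Rab, focal adhesion and stem cell genes and monocyte markers.

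**Figure D4:**
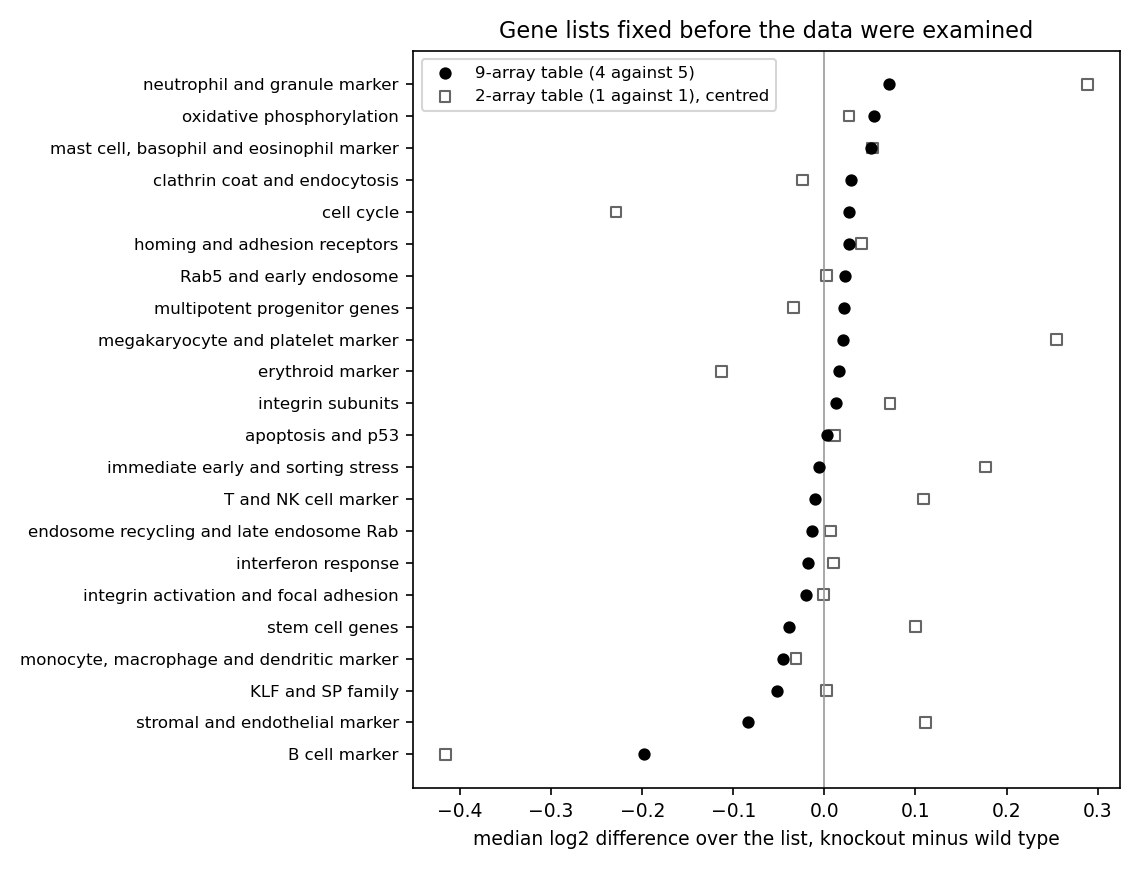
Median log2 difference (knockout minus wild type) of the reported gene lists in the 9-array table (filled circles, 4 against 5 arrays) and in the 2-array table (open squares, 1 against 1, centred on the median of all genes). B cell markers have the lowest median in both, -0.20 and -0.42, and no list passes the adjusted threshold.

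Sex-linked genes differed between arrays of both genotypes. Knockout replicates 3 and 4 and wild-type replicate 5 had Xist at 11.05, 11.12 and 11.06 with Y-linked means of 4.12, 4.22 and 4.42. Wild-type replicates 2, 3 and 4 had Y-linked means of 8.04, 7.90 and 8.04 with Xist at 4.88, 4.74 and 5.47. Knockout replicates 2 and 5 and wild-type replicate 6 carried both, with Xist at 9.59, 10.59 and 10.49 and Y-linked means of 7.73, 7.09 and 7.09, as did both arrays of the 2-array table. Y-linked signal without Xist was seen in wild-type arrays only among the 11, so these signals were not balanced between the genotypes. Leaving out the 3 arrays that carried both gave 1850 transcript clusters at unadjusted p under 0.05, with 0 after adjustment, and 7 lists: cell cycle, mast cell, oxidative phosphorylation, erythroid and homing lists higher, and interferon and stromal lists lower. None of the 7 passed in that fit, with a lowest adjusted p = 0.492 with an estimated correlation.

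**Figure D5:**
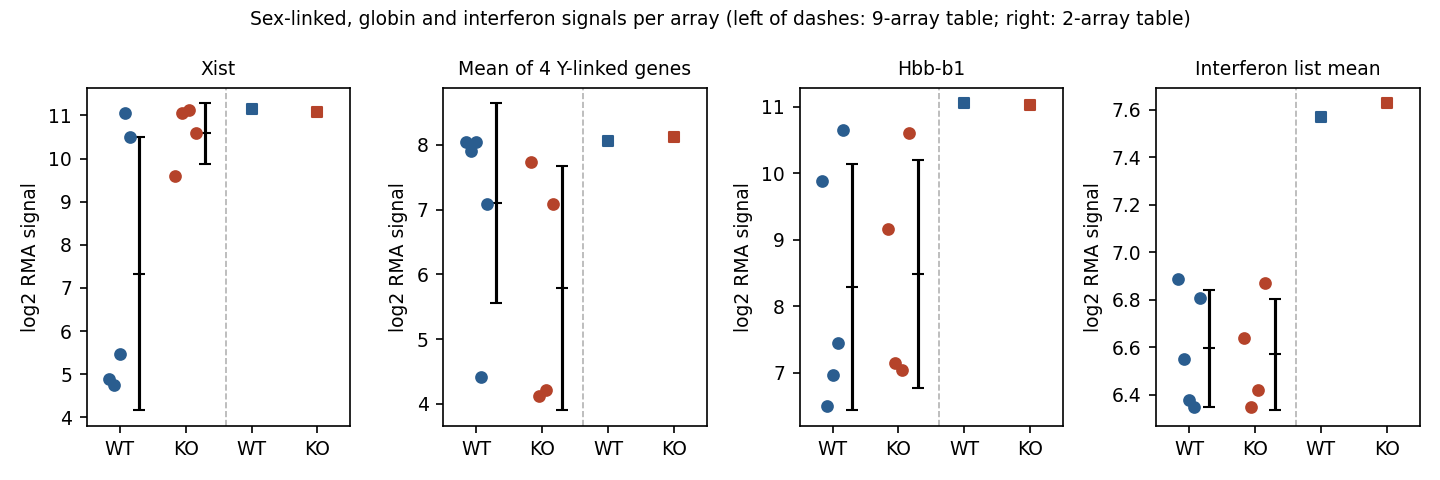
Log2 RMA signal of Xist, the mean of 4 Y-linked genes, the globin Hbb-b1 (mean of the rows so named) and the interferon list mean, with 1 point per array and the mean ± SD beside the wild-type (WT, n = 5) and knockout (KO, n = 4) arrays; squares right of the dashed line are the 2-array table, normalized separately. Hbb-b1 ranges from 6.50 to 10.65 over the 9 arrays, within both genotypes.

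The 2 tables differed from each other more than the genotypes did. With genotype and table in 1 limma model over all 11 arrays, 17555 transcript clusters differed between the tables, 60.7% of those tested, with a median difference of 0.43. After quantile normalization over all arrays 9444 still differed.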

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

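Apart from the screen for outlying arrays, the tests in this part were chosen after the results were seen. In 110 groups of 4 or 5 arrays screened, 11 held an array far from the others, where chance gives about 6. Knockout replicate 5 stood high in Rab5b at 7.47, in Phf12 at 8.30 and in the mean of multipotent progenitor genes at 7.95. Knockout replicate 4 was high in Itgb1 at 10.02, knockout replicate 2 low in Rpusd3 at 5.95 and knockout replicate 3 low in Klk1b7-ps at 3.73. Wild-type replicate 5 was low in Micu2 at 6.66 and in the focal adhesion list mean at 7.11. Wild-type replicate 3 was low in Ccrl2 at 6.00 and high in Tram2 at 7.63, and wild-type replicate 2 was low in Klk1b21 at 6.41.

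The 9 arrays were also split in other ways into 4 and 5, and the 100 splits drawn include the real one. No split can give fewer than the 0 transcript clusters that passed adjustment in the real one, so that 100 of the 100 splits drawn gave as many says nothing about it; the highest other split gave 129. At unadjusted p under 0.05, 32 of the 100 splits, with the real one counted among them, gave at least its 1181. The highest other gave 3697, so chance cannot be excluded for that count. The split with both highest counts put knockout replicates 2 and 5 with wild-type replicates 2 and 6, which points to a structure of the samples other than genotype.

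Of 15 Klk1 and Klk1b rows, 4 had values lower by over 0.3 in knockout in both tables, against 0 of 12 other Klk rows; the 4 were noticed in the data, with no list fixed beforehand, and did not pass adjustment. Klk1b22, chosen after its values were seen, lay below the negative-control median in 4 of 4 knockout arrays, so its log2 difference of -2.55 (95% interval -3.80 to -1.30, limma adjusted p = 0.916), and of -4.67 in the 2-array table, is set against background and its size is uncertain; Klk1b7-ps lay below it in both groups and is not weighed further. Strain DNA linked to the Klf5 allele is argued against, since 0 of the 4 genes lie on its chromosome in GRCm38.p6. Sex as the whole cause was examined for Klk1b22 and Klk1b21 with Xist and Y-linked levels in the limma model. There 2 of 2 intervals stayed below 0, at -2.42 (-4.14 to -0.70) and -1.05 (-1.45 to -0.65). This argues against it only as far as that model holds. No knockout array had Y-linked signal without Xist, so the model extrapolates there, and both genes were picked for low knockout values. Sex stays open for Klk1, which went from -0.38 (SE 0.11) to -0.32 (SE 0.15) with an upper bound of 0.025, more through a larger error than a smaller difference, and as a part of Klk1b22, which in the arrays with Xist alone was at 5.40 in wild type and at 4.25 and 5.50 in knockout, though at -4.35 between knockout replicate 5 and wild-type replicate 6, which differed by 0.10 in Xist. Chance, strain DNA elsewhere and probes shared between paralogs, whose sequences were not used here, stay open too, so loss of Klf5 may be the source only as an untested hypothesis.

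The 2-array pair resembled knockout replicate 5 and wild-type replicate 6. Of 20 knockout minus wild-type differences in the 9-array table, that pair's correlated best with the 2-array difference across transcript clusters (r = 0.309, next 0.168; genes are not independent replicates), and 82.1% of its 95 differences of over 1 log2 unit had the same sign. Repeat hybridisation of the same RNA may give this, and it cannot be told apart from related animals because the labels tie no array to an animal. Without that pair Klk1b22 had a difference of -2.07 (-3.35 to -0.78) and Klk1b21 one of -0.93 (-1.31 to -0.55). Without it 28 transcript clusters at unadjusted p under 0.05 were lower by over 0.3 in both tables, where 25.4 would be expected of unrelated tables.

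B cell markers had lower values in knockout without passing the test, and the list mean followed the Hbb-b1 and interferon list means of the 9 arrays: 5.47 and 5.36 in knockout replicates 2 and 5 and 5.60 and 5.95 in wild-type replicates 2 and 6, against 5.12 to 5.21 in the other 5 arrays. Within both sets of arrays each knockout value lay below each wild-type value. In the other 5 arrays every list mean lay below the negative-control median of its array, so the order there is weak. Mature B cells among the sorted wild-type cells cannot be told apart from other sources here: 8 mature B cell genes outside the list had a median of -0.053 against -0.198 for the list, and the gap of 0.145 exceeded the genes' median absolute deviation of 0.095, the spread first used, but not their median standard error of 0.192, used next, and over the 9 arrays it was 0.127 (95% interval -0.059 to 0.312, two-sided exact permutation p = 0.135). The 8 were H2-Ab1 at -0.27, H2-Eb1 at -0.17, Cd37 at -0.06, H2-Aa at -0.06, Cd74 at -0.05, Ciita at 0.002, Cd83 at 0.02 and Fcer2a at 0.07. They are not specific to mature B cells: Cd74, H2-Aa, H2-Ab1 and H2-Eb1 also stand in the monocyte, macrophage and dendritic list. The other mature B cell genes, Ms4a1, Cr2, Cd22, Cd72, Bank1 and Blk, were in the B cell list itself. The gap therefore does not measure mature B cells alone. A lineage-negative sort should remove mature B cells. Genes of early B lymphoid progenitors, 9 of 12 of them also in the B cell list, had a median of -0.313, with 9 of 12 lower and a fry p of 0.373, against -1.234 with 12 of 12 lower in the 2-array table, which may repeat RNA of the related pair and is then not separate evidence. Without the pair of arrays nearest to the 2-array table the camera adjusted p of the B cell list was 0.517, from 0.000145 to 0.996 over the alternatives. The lowest came from all 11 arrays with the table term, where the camera adjusted p was 0.944 with an estimated correlation. A lower share of B lymphoid progenitors therefore remains a hypothesis that may rest on that pair.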

How the results depend on the processing

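Alternatives chosen after the data were seen were the block from the column-name number, the Xist and Y covariates, and both fits that left out named arrays. Of 719 values of 30 genes under the alternatives, 717 kept their direction and side of the threshold. The 24 genes named by the fixed rule were picked for groups that did not overlap, so leaving out arrays could not reverse them. For these genes the count is therefore not a test of stability. Itgb2 turned to -0.077 without the arrays carrying both Xist and Y transcripts and to -0.022 without knockout replicate 2; leaving out each array gave -0.022 to 0.113. The count of changed transcript clusters was 0 in every fit with adjustment. It was 1150 for the methods' t-test at unadjusted p under 0.05, and 121 at unadjusted p under 0.05 with a fold of at least 1.5. The unadjusted count was 176 over all 11 arrays without a table term, 614 with the filter on dim rows, which tests fewer rows, and 1850 without the arrays carrying both Xist and Y transcripts. Leaving out each array gave 798 to 1698. The count of shifted lists was 3 over all 11 arrays with the table term and 3 without it, 4 with array weights, 4 with the Xist and Y covariates, 7 without the arrays carrying both, and 0 to 8 leaving out each array. In the same fits 0 lists passed, at a lowest adjusted p = 0.291 with an estimated correlation. The 11-array fits may count the same RNA more than once. Over 25 alternatives the mast cell list passed in 9 (adjusted p 0.00346 to 0.996) and the B cell list in 7 (0.000145 to 0.996). Klk1b21 came nearest to passing without wild-type replicate 2, at an adjusted p of 0.0732. That replicate was its outlying wild-type array, at 6.41 against 6.88 to 6.92 in the others. Without it the difference was larger, at -1.05, and the spread of the wild-type arrays smaller. Replicate numbers were not taken to pair the samples, since no numbering had every correlation over 0.1: deviations of arrays with the same number in the titles correlated at 0.133, 0.11, 0.12 and -0.242, in the descriptions at -0.051, 0.066, 0.121 and 0.404, and in the column names at 0.133, 0.066, 0.121 and 0.404. The highest was knockout replicate 5 with wild-type replicate 6. A replicate block from titles or descriptions left 0 transcript clusters, and a replicate block from the column-name number gave 2 lists, the B cell list lower (adjusted p 0.0044) and the mast cell list higher (0.0269). In that block neither passed, both at adjusted p = 0.973 with an estimated correlation. Quantile normalization over all arrays gave 9444 transcript clusters that differ between the tables.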

Other observations

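The tests in this part were chosen after the data were seen. Of 553 biological process terms in the files' annotation, 8 passed camera with a preset correlation, each with higher values in knockout, and with an estimated correlation their adjusted p was 0.960. Ribosome biogenesis, with 53 genes, had a median log2 difference of 0.14 (camera adjusted p = 0.0176), and DNA replication, with 106 genes, one of 0.06. In the 2-array table the medians of these terms were -0.002 and -0.050.

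The globin Hbb-b1 and interferon response genes varied between arrays of both genotypes. Hbb-b1 was at 9.16 and 10.61 in knockout replicates 2 and 5, and at 9.88 and 10.65 in wild-type replicates 2 and 6. It lay between 6.50 and 7.44 in the other arrays of the 9-array table. The interferon list mean was 6.64, 6.87, 6.89 and 6.81 in the same 4 arrays, and between 6.35 and 6.55 in the others. The closest arrays of the table, knockout replicate 5 and wild-type replicate 6, were of different genotypes, with a correlation of 0.995 across genes against a highest of 0.993 within a genotype.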
